A study of Mus musculus with 2 samples.

How the data were processed

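The 2 libraries were made from mouse salivary glands with the droplet-based Chromium Next GEM Single Cell 5' v2 kit, 1 from each region, and the labels give no other replicate. The deposited values are raw counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 on build mm10, per the submitters' processing notes. Further upstream steps, such as read trimming or any correction for free RNA, are not given in the sources used here. The values were checked to be whole numbers of at least 1, and the barcodes of a file to sum to different totals. Libraries of cell surface proteins or immune receptors, which the kit allows, were not used here. The groups were taken from the labels. The files paired 32285 gene identifiers with names, and 32158 of them were found in the GENCODE M21 annotation of the same build, which gave the coordinates. All genes given with coordinates are annotated there as protein coding, except Muc19, which is annotated as a processed transcript.

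Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. This left 12573 lymphoid and 1255 non-lymphoid barcodes, and 429 and 154 barcodes had fewer genes and 388 and 192 a higher mitochondrial share. Scrublet, run per library in scanpy 1.11.5, removed 294 (2.34%) and 17 (1.35%) barcodes as doublets. Genes in at least 3 cells were used. Both libraries were clustered together after scaling to 10000 UMIs per cell and taking logs, with 2000 variable genes that left out antibody and T cell receptor variable segments, 30 principal components, 15 neighbours, and Leiden clustering at resolution 1.0 with python-igraph 0.11.9. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. No correction for library was made, because library and region are the same split.

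The 31 clusters were named from marker lists fixed with the gene lists below. A class scored the mean over its markers of the log2 of CPM with 5 added, relative to the median cluster, and a name needed at least 3 markers each found in 10% of the cells. A cluster was left unnamed where a second lineage scored at least 0.62 of the best, or where its median depth was far below its library's and none of its 10 top genes was a marker of its own. Related types whose scores came within 0.85 of each other shared a name. In the second clustering of lymphocytes that limit was 0.8, subclusters with at least 2 markers of another lineage among the top genes or a score under 0.5 stayed unnamed, and NK or innate lymphoid names were not given to subclusters mostly positive for Cd3e. These limits were set after the clusters were seen, and the value of 0.62 left a mixed cycling cluster unnamed, so 0.60 and 0.65 were tried as well. The limits left 4 clusters unnamed. The T cell cluster with Il17a had as many marker genes of group 3 innate lymphoid cells as of T cells among its top genes and was kept with the T cells. T and NK/ILC1 cells were clustered again into 15 subclusters and B cells into 13, with the same settings. Clusters are referred to by marker genes, and levels of those genes within their cluster are not independent of the clustering.

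With 1 library per region, no test was made and cells were not used as replicates. For each class with at least 50 cells in each library, namely macrophages, blood endothelial cells, NK/ILC1 cells, T cells and acinar cells, UMIs were summed per library and divided by the library's total of the class to give CPM. Intervals at 95% were exact Clopper-Pearson for shares, exact Poisson for counts and exact conditional binomial for ratios. A gene at 0 in 1 library was given a floor of 3 counts over the class and is reported as a lower bound, and a share of 0 is reported with the limit that 3 counts allow. Depth limited precision most in the non-lymphoid NK/ILC1, T and acinar cells, with 606472, 918021 and 1556884 UMIs over 64, 141 and 63 cells.

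Before the data were examined, the comparisons, the settings, 26 gene lists and the rule for named genes were fixed. The rule took in each class the 10 genes with the largest ratio in each direction among genes with at least 50 CPM and 20 UMIs in the library where they were higher. The interval of the ratio had to exclude 1 and the class level had to be at least 0.5 times the level of the whole library, which leaves out genes brought by free RNA. Ribosomal, mitochondrial and receptor variable genes were left out. It also took up to 4 members of each list with the highest level and 11 genes always given for NK/ILC1 cells. The same rule without the free RNA limit was used over all cells. A list's median log2 ratio was taken over members with at least 20 UMIs and compared with 10000 random lists matched on expression, as a description of these libraries, and its range came from 200 Poisson redraws. Of 118 pairs of list and class, the 18 in the figure were chosen after the medians were seen, as were the few further medians given beside them. They come from the lists of tissue residency, circulation and naive, cytotoxic granule, type I interferon, interferon gamma, MHC class II, follicular helper, inflammatory, tissue repair, cell cycle, ion and water secretion, salivary secretory, and dissociation and heat shock genes.

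Gzma was also compared after each cell was thinned to 1000 UMIs, with at least 2 UMIs per positive cell, and in a gate of cells picked by UMIs of marker genes. Free RNA was estimated per class from genes of cells that the class should not contain. Receptor segments were called per cell where 1 segment held 80% of at least 5 antibody or 2 T cell receptor UMIs. The calculation of levels was run on simulated Poisson counts, the model that the intervals assume, in which 200 genes of each class were changed by 2 or 4 times. Between 95.9% and 96.4% of intervals then held the true ratio, which that model largely sets. Intervals excluded 1 for 57.9% of acinar and 87.9% of macrophage genes changed by 2 times, and for 90.2% and 100% of those changed by 4 times. The simulation had no spread between cells, so it checks the calculation only. It does not show how the intervals hold for genes whose UMIs lie in few cells. The alternatives tried were at least 500 genes, at most 5% or 20% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2.0, each library clustered alone, 50 principal components, no filter on UMIs, stricter minimums, other scalings of levels and subtraction of free RNA. Further alternatives, restricted to parts of a class or to fewer genes, were added after the data were seen.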

Results

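RNA of single cells was sequenced from mouse salivary glands as 2 libraries, 1 from a lymphoid cluster region and 1 from the non-lymphoid cluster region. A lymphoid cluster is an aggregate of lymphocytes inside an organ that is not a lymphoid organ. The series title names granzyme A, type 1 innate lymphoid cells and the aged submandibular gland, while the labels give salivary glands and no age. The lymphoid library held 13109 cell barcodes with 77235068 UMIs (unique molecular identifiers, which count captured RNA molecules), and the non-lymphoid library held 1471 barcodes with 13463993 UMIs. After filtering, 12279 and 1238 cells remained, with medians of 3417 and 8105 UMIs and of 1421 and 2678.5 genes per cell. With 1 library per region, no difference was compared with a spread between replicates, and a cluster that came mostly from 1 library may reflect that library. Shares are given with exact Clopper-Pearson 95% intervals. Levels are the UMIs of a cell class summed per library and scaled so that all genes of a class have the same total (CPM), with exact Poisson 95% intervals, and ratios of levels have exact conditional binomial 95% intervals. All of these intervals cover counting error only.

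The first comparison asked which classes the captured cells of each library belonged to. Shares are of the cells kept after the filters and need not be those of the tissue. B cells, plasma cells and T cells had larger shares in the lymphoid library, and macrophages and blood endothelial cells in the non-lymphoid library. B cells were 21.3% (20.5 to 22.0) of the lymphoid library, 2610 cells, and 0.0808% (0.00205 to 0.449) of the non-lymphoid library, a single cell, for a ratio of 263 (47.2 to 10398). Plasma cells, which secrete antibody, were 6.24% (5.82 to 6.68) against 0.0808%, with 766 cells and 1 cell and a ratio of 77.2 (13.8 to 3054). The ratio was 20.2 (8.61 to 62.2), with 5 non-lymphoid cells, with the limit for a second lineage at 0.65, where a mixed cycling cluster took the plasma cell name. T cells were 32.1% (31.3 to 32.9) against 11.4% (9.67 to 13.3), a ratio of 2.82 (2.38 to 3.36). Natural killer cells and type 1 innate lymphoid cells, grouped as the NK/ILC1 class, were 3.01% (2.72 to 3.33) against 5.17% (4.004 to 6.55), and so took a share 1.72 times (1.29 to 2.24) as large in the non-lymphoid library. This difference was smaller in several alternatives. The NK/ILC1 shares were 3.88% against 5.17% with each library clustered alone and at resolution 0.5, and 4.01% against 5.42% with at most 5% mitochondrial UMIs. Lymphocytes and plasma cells together were 62.6% (61.7 to 63.4) against 16.7% (14.7 to 18.9).

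Macrophages were 12.7% (12.1 to 13.3) of the lymphoid and 41.8% (39.1 to 44.6) of the non-lymphoid library, 3.29 times (2.97 to 3.64) as large a share in the latter. Blood endothelial cells, which line vessels, were 6.47% (6.05 to 6.92) against 24.3% (21.9 to 26.8). Cells named ductal were 0.309% (0.219 to 0.425) against 2.91% (2.04 to 4.003), all from 1 cluster with Ascl3 and Foxi1 among its top genes. They are not all duct cells, since a cluster marked by Klk1 genes, which scored for ductal cells and macrophages, stayed unnamed. That cluster was 1.36% against 3.63%. A cluster with monocyte and conventional dendritic cell genes was 3.74% (3.41 to 4.09) against 0.323% (0.0881 to 0.825). The smaller classes were basal epithelial cells with 0.725% against 1.70%, myoepithelial cells with 0.961% against 1.13%, fibroblasts with pericytes or smooth muscle cells with 1.02% against 1.62%, and Schwann cells with 0.195% against 0.242%. Acinar cells, which secrete saliva, were 2.08% (1.83 to 2.34) against 5.09% (3.93 to 6.46), but the direction of this difference depended on where the cells of 1 unnamed cluster were placed. Clusters left unnamed, mostly because they held RNA of more than 1 lineage, were 9.19% (8.69 to 9.72) of the lymphoid and 4.12% (3.08 to 5.38) of the non-lymphoid library. The filters passed 95.9% of the lymphoid and 85.3% of the non-lymphoid barcodes, and the non-lymphoid cells had more UMIs in the median, except acinar cells, with 21640 UMIs in the lymphoid and 8822 in the non-lymphoid library.

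**Figure D1:**
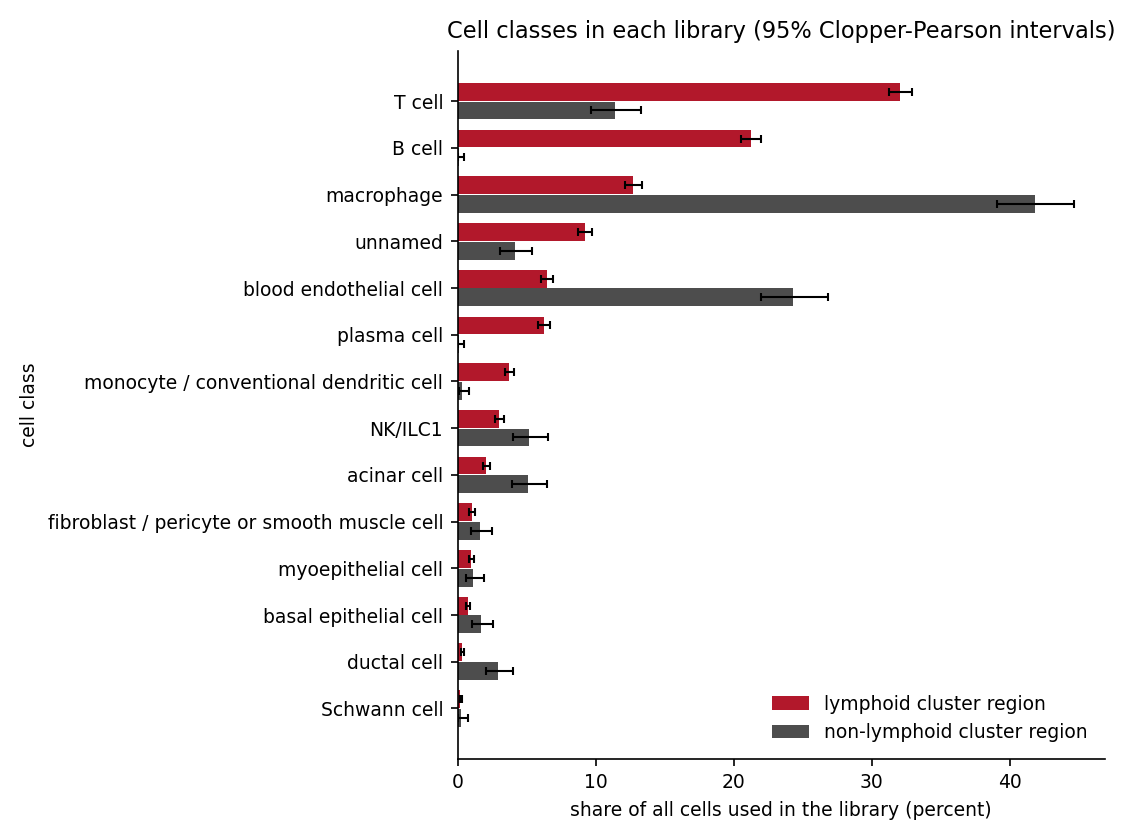
Share of all cells used in each library (percent, horizontal axis) for each cell class (vertical axis), with exact Clopper-Pearson 95% intervals and 1 library per region. T cells were 32.1% of the lymphoid and 11.4% of the non-lymphoid library, and macrophages were 12.7% and 41.8%.

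The second comparison asked which T cells, NK cells and innate lymphoid cells each library held, among 4309 lymphoid and 205 non-lymphoid cells that were clustered again. Regulatory T cells, which restrain immune responses, were 11.2% (10.2 to 12.1) of these cells in the lymphoid library and 1.46% (0.303 to 4.22) in the non-lymphoid library, a ratio of 7.63 (2.59 to 37.1). A CD4 subcluster marked by the cytokine gene Il21, which also scored for regulatory T cell genes, was 14.0% (12.97 to 15.1) against 1.95% (0.534 to 4.92). A subcluster of CD8 T cells with naive T cell genes such as Lef1 and Ccr7 held 655 lymphoid cells, 15.2% (14.1 to 16.3), and 0 non-lymphoid cells, which allows up to 1.46%. Gamma delta T cells were 3.55% (3.02 to 4.15) against 0.976% (0.118 to 3.48), and group 2 innate lymphoid cells were 1.25% (0.943 to 1.63) against 1.46% (0.303 to 4.22). CD8 T cells as a whole were 27.2% (25.9 to 28.6) against 36.1% (29.5 to 43.1), and other CD4 T cells were 27.8% (26.5 to 29.2) against 24.9% (19.1 to 31.4). The latter shares pooled subclusters that went opposite ways. The CD4 subcluster marked by Zfp683 was 5.80% (5.12 to 6.54) against 23.4% (17.8 to 29.8). The remaining CD4 subclusters were 11.9% and 10.1% against 0.976% and 0.488%, with 2 and 1 non-lymphoid cells. Unnamed subclusters were 6.85% (6.11 to 7.64) against 1.95%.

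Most NK/ILC1 cells fell into a pair of subclusters, marked by Gzmc with 81 and by Klra8 with 255 of the 370 lymphoid cells, and with 51 and 13 of the 64 non-lymphoid cells. The subcluster marked by the granzyme genes Gzmc and Gzmb scored for genes of type 1 innate lymphoid cells and, nearly as high, of NK cells. It was 2.23% (1.81 to 2.71) of T and NK/ILC1 cells in the lymphoid and 24.9% (19.1 to 31.4) in the non-lymphoid library, 11.2 times (7.79 to 15.8) as large a share in the latter. The subcluster marked by the NK receptor gene Klra8 was named NK cell and was 5.94% (5.25 to 6.69) against 6.34% (3.42 to 10.6), a ratio of 0.937 (0.538 to 1.78). Within the NK/ILC1 class the Klra8 subcluster held 68.9% of the lymphoid cells and the Gzmc subcluster held 79.7% of the non-lymphoid cells. Because Gzmc and Gzmb also differed in level between the libraries, these subcluster sizes are not independent of those genes.

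Among the 2610 B cells of the lymphoid library, naive B cells were 51.7% (49.7 to 53.6), B1 cells 18.6% (17.1 to 20.1) and cells scoring for both B1 and age-associated B cell genes 6.48% (5.56 to 7.49). Cells with germinal centre genes, which mark B cells that mutate and select their receptors, were 4.41% (3.65 to 5.27). B cell subclusters that met no name were 18.9% (17.4 to 20.4). The single non-lymphoid B cell gave no comparison.

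The third comparison asked whether granzyme A, the protease in the series title, differed between the regions in NK/ILC1 cells. Gzma was 1306 CPM (1250.3 to 1363) in NK/ILC1 cells of the lymphoid library and 338 CPM (293 to 388) in those of the non-lymphoid library, a ratio of 3.86 (3.35 to 4.48) from 2081 and 205 UMIs. The gene (ENSMUSG00000023132) lies on chromosome 13 from 113093825 to 113100981 in build mm10. In the Klra8 subcluster Gzma was 1716 against 412 CPM, a ratio of 4.16 (3.22 to 5.48), although the non-lymphoid value came from 60 UMIs in 4 of 13 cells. In the Gzmc subcluster it was 544 against 315 CPM, a ratio of 1.73 (1.40 to 2.14), which fell to 1.26 (0.999 to 1.59) without the lymphoid cell that held 65 of the 226 UMIs. The share of Gzmc subcluster cells with a Gzma UMI went the other way, at 12.5% (6.63 to 20.8) of lymphoid and 15.7% (7.02 to 28.6) of non-lymphoid cells. Within the lymphoid library, Gzma was 3.16 times (2.75 to 3.64) as high in the Klra8 as in the Gzmc subcluster, and within the non-lymphoid library 1.31 times (0.953 to 1.78).

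A Gzma UMI was found in 50.5% (45.3 to 55.7) of lymphoid and 18.8% (10.1 to 30.5) of non-lymphoid NK/ILC1 cells, at median depths of 3878 and 9398 UMIs. With each cell thinned to 1000 UMIs the shares were 39.4% and 15.6%. Background differed between classes. A UMI was found in 0.126% of lymphoid and 0 of 301 non-lymphoid blood endothelial cells, which should lack Gzma, at median depths of 2505 and 4949 UMIs. It was also found in 2.87% (1.81 to 4.32) of lymphoid plasma cells, at a median depth of 19706 UMIs, and in 2 of 38 ductal cells, and 1 of 89 basal cells held 84 UMIs.

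The fourth comparison asked which classes held Gzma. NK/ILC1 cells held 60.4% of the lymphoid library's 3444 Gzma UMIs and T cells held 21.8%, while in the non-lymphoid library T cells held 65.3% of 599 UMIs and NK/ILC1 cells 34.2%. Over all cells the libraries had nearly the same level, 46.4 CPM (44.9 to 48.0) against 49.2 CPM (45.3 to 53.3). T cells thus went the other way from NK/ILC1 cells, with 60.5 CPM (56.3 to 65.0) in the lymphoid and 426 CPM (385 to 470.3) in the non-lymphoid library, a ratio of 0.142 (0.126 to 0.161). This T cell level rested on few cells, as 1.19% (0.878 to 1.58) of lymphoid and 10.6% (6.08 to 16.9) of non-lymphoid T cells had a Gzma UMI, and the 391 non-lymphoid UMIs came from 15 cells, and without the non-lymphoid cell with the most, 87 UMIs, the ratio was 0.182 (0.159 to 0.208). The 15 cells belonged to a CD8 T cell subcluster with the interferon response genes Ifit1 and Ifit3 among its top genes. This subcluster was 5.85% of lymphoid and 32.7% of non-lymphoid T and NK/ILC1 cells. In it Gzma was 240.2 CPM in the lymphoid and 831 CPM in the non-lymphoid library. A small lymphoid subcluster of 12 CD8 T cells, with Gzma among its marker genes, held 591 Gzma UMIs, 17.2% of the library's total. The share of lymphoid T cells with Gzma was not above that of the deeper plasma cells, a comparison at unlike depth. With each cell thinned to 1000 UMIs the order changed, at 0.606% (0.384 to 0.908) of T cells and 0.264% (0.0320 to 0.951) of plasma cells. Those intervals overlapped.

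**Figure D2:**
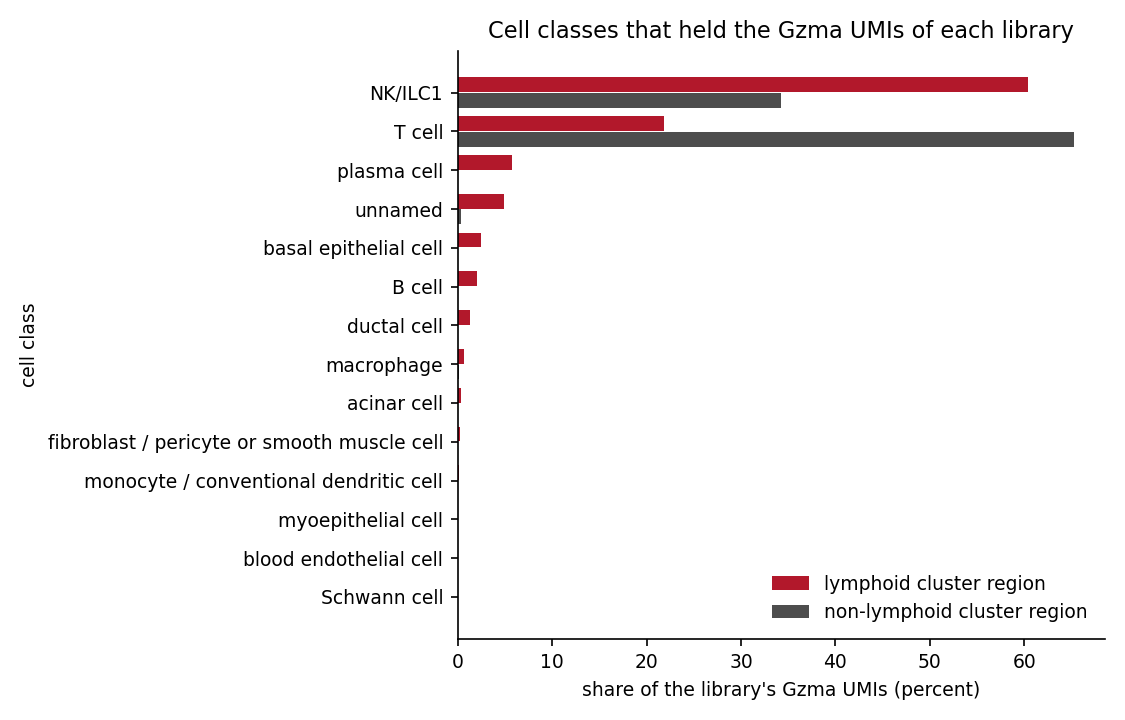
Share of each library's Gzma UMIs (percent, horizontal axis) that lay in each cell class (vertical axis), with 1 library per region. NK/ILC1 cells held 60.4% of the lymphoid and 34.2% of the non-lymphoid Gzma UMIs, and T cells held 21.8% and 65.3%.

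The remaining comparisons asked how gene levels within a class differed between the regions. In NK/ILC1 cells, Gzmb moved opposite to Gzma. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), another killing protease, was 563 CPM in the lymphoid and 1913 CPM in the non-lymphoid library, 3.39 times (3.11 to 3.71) as high in the latter. Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656) was 1212 against 2092 CPM. Further genes tied to tissue-resident type 1 innate lymphoid cells were higher in the non-lymphoid library: the integrin gene Itga1 at 89.7 against 265 CPM, the chemokine receptor gene Cxcr6 at 125 against 249 CPM, and the death ligand gene Tnfsf10 at 67.1 against 171 CPM. Itga2, an integrin gene of circulating NK cells, was higher in the lymphoid library at 68.4 against 14.8 CPM, a ratio of 4.61 (2.34 to 10.3). Gzmk had 34 UMIs against 1, a ratio of 12.9 (2.17 to 526). Prf1, which encodes perforin, the interferon gamma gene Ifng, the NK receptor gene Ncr1 and the transcription factor gene Eomes differed little, with ratios of 1.12, 0.997, 1.12 and 1.19 over the whole class and intervals that included 1. In the Klra8 subcluster Ifng was 2.78 times (1.43 to 6.19) and Eomes 0.635 times (0.480 to 0.851) as high, against 13 non-lymphoid cells. Most NK/ILC1 cells were of the Klra8 subcluster in the lymphoid and of the Gzmc subcluster in the non-lymphoid library, and in the Gzmc subcluster alone the differences in Gzmb, Gzmc, Itga1, Cxcr6 and Tnfsf10 were smaller or changed sign. There Gzmb was 1621 against 2484 CPM and Itga1 199.6 against 328 CPM, Gzmc went the other way at 4401 against 2751 CPM, and the ratios of Cxcr6 and Tnfsf10 were 1.21 (0.965 to 1.53) and 0.809 (0.573 to 1.14). Gzmc and Gzmb themselves mark that subcluster.

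**Figure D3:**
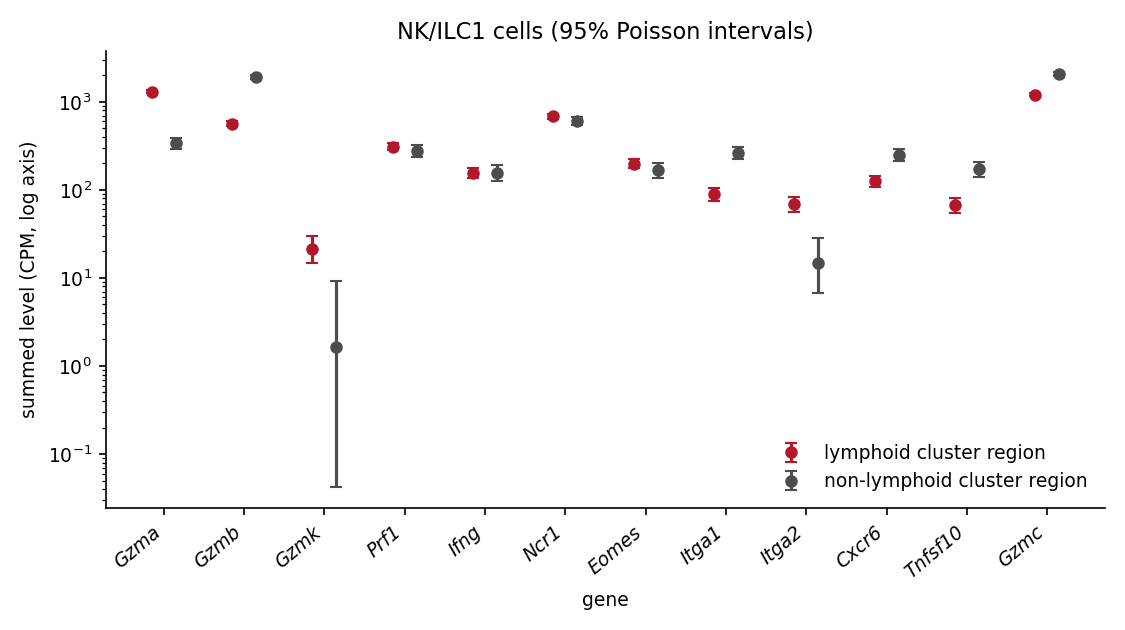
Levels of 12 genes in NK/ILC1 cells (CPM of summed UMIs, log axis) in each library, with exact Poisson 95% intervals and 1 library per region. Gzma was 1306 CPM in the lymphoid and 338 CPM in the non-lymphoid library, and Gzmb was 563 and 1913 CPM.

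Circulation and naive genes had a median log2 ratio of lymphoid over non-lymphoid of 2.11 (1.67 to 2.51) in NK/ILC1 cells, with 9 of 9 genes higher in the lymphoid library. The medians of MHC class II and salivary secretory genes, which other cells make, were higher still at 2.27 and 4.002. After subtraction of free RNA, 9 of 9 circulation and naive genes were still higher in the lymphoid library. Klf2, which controls exit from tissues, was 834 against 257 CPM, and Tcf7 was 219.6 against 36.3 CPM. Tissue residency genes were lower in the lymphoid library in 9 of 11 genes, with a median of −1.18 (−1.41 to −0.93), and with smaller medians of −0.46 in the Gzmc and −0.51 in the Klra8 subcluster. Rgs1 was 879.7 against 2788 CPM and Rgs2 177 against 401 CPM, while Cd69 went the other way at 422 against 336 CPM. Type I interferon response genes were higher in the lymphoid library over the whole class, with a median of 0.89 (0.54 to 1.09). Of 12 genes 11 were higher there, 6 with an interval of the ratio above 1, and Bst2 was 145 against 64.3 CPM. The direction held in the Gzmc but not in the Klra8 subcluster, where the median was −0.20. In T cells the median was −1.16 over the class and −0.95 in the CD8 cluster, but 0.64 in the Zfp683 cluster. A CD8 T cell subcluster with Ifit1 and Ifit3 among its top genes was 5.85% of lymphoid and 32.7% of non-lymphoid T and NK/ILC1 cells. Dissociation and heat shock genes, which rise when tissue is digested, had a median of −0.23 in NK/ILC1 cells, the direction of the residency genes. Cytotoxic granule genes had a median of 0.13 (0.01 to 0.29), at percentile 50.7 of random lists, with Nkg7 higher in the lymphoid library and Gzmb and Gzmc higher in the non-lymphoid library, and this median was −0.06 when cells needed at least 500 genes. Of the 10 named genes higher in the lymphoid library, Il18r1, a cytokine receptor gene, was 114 against 23.1 CPM and Calhm6 was 7.38 times as high. Lyz2 was led by 1 cell with 422 of its 691 UMIs, and its ratio without that cell was 9.38. Of the 10 named genes higher in the non-lymphoid library, 7 were higher there in all 5 classes compared, among them Il31ra, Fgfr2 and Lars2. Of the others, the adhesion gene Cdh1 was 26.4 against 153 CPM.

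T cells of the lymphoid library were richer in genes of circulating and follicular helper T cells, and those of the non-lymphoid library in genes of tissue-resident T cells. Circulation and naive genes had a median log2 ratio of 2.02 (1.79 to 2.19), with 9 of 9 genes higher in the lymphoid library. Salivary secretory and MHC class II genes, made mainly by other cells, had medians of 1.84 and 0.95 in the same T cells. After subtraction of free RNA, 9 of 9 circulation and naive genes were still higher in the lymphoid library. The circulation median was 2.80 in the CD8 cluster but 0.42 in the cluster marked by Zfp683. Klf2 was 1107 against 272 CPM, Tcf7 467 against 124 CPM and Lef1 209 against 50.1 CPM. Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), the receptor for homing to lymphoid tissue, was 154 against 4.36 CPM, a ratio of 35.3 (13.8 to 130) from 1906 and 4 UMIs. Tissue residency genes had a median of −1.71 (−1.89 to −1.51), with 10 of 11 genes higher in the non-lymphoid library, and dissociation and heat shock genes went the same way with a median of −0.32. Rgs1 was 328 against 1603 CPM and Cxcr6 152 against 645 CPM. Zfp683 (ENSMUSG00000049410, chromosome 4, 134053838 to 134058996), a transcription factor gene of resident T cells, was 17.3 against 198 CPM, and Itga1 was 19.8 against 212 CPM. Cdh1 and Coro2a were also higher there, with log2 ratios of −4.22 and −3.53.

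Follicular helper and germinal centre genes had a median of 0.60 (0.46 to 1.17) in T cells, with 8 of 9 genes higher in the lymphoid library, and of 0.18 in the Zfp683 cluster. Il21, which drives B cell help, was 62.0 against 9.80 CPM, a ratio of 6.32 (3.31 to 13.9), Icos was 204 against 135 CPM and Sh2d1a 203 against 117 CPM, while Pdcd1 was 182 against 197 CPM. Within the cluster of Il21 and Pdcd1 T cells, with 825 lymphoid and only 6 non-lymphoid cells, Il21 was 237 against 216 CPM. The Il21 ratio over all T cells thus went largely with the share of that cluster. Spp1 was 434 against 46.8 CPM, a ratio of 9.27 (6.87 to 12.8). Of its lymphoid UMIs 5368 were in the same cluster, where it was 1717 against 1033 CPM. Areg, a growth factor gene of regulatory T cells, was 58.9 against 2.18 CPM, a ratio of 27.0 (7.45 to 223) with 2 non-lymphoid UMIs. Ccl1, Nrgn, Dapl1, Cd9 and Il1r2 were also higher in the lymphoid library, by 24.7, 18.8, 18.3, 12.9 and 10.1 times, but 1 cell held 307 of the 668 Ccl1 UMIs, and without it that ratio was 13.4. Cytotoxic granule genes had a median of −0.86 (−1.23 to −0.75), with Nkg7 at 603 against 1393 CPM and Ctsw at 295 against 932 CPM, and with Srgn going the other way. The same list had a median of 0.37 in the cluster marked by Zfp683, so the direction over all T cells did not hold in that cluster. The red cell gene Hbb-bs met the rule for named genes only because 1 lymphoid cell held 1264 of its 1266 UMIs. T cells came from different clusters, as 50 and 74 of the 141 non-lymphoid cells were in the Zfp683 and Gzmk clusters, which held 293 and 716 of the 3939 lymphoid cells.

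Macrophages of the lymphoid library had more cell cycle RNA and those of the non-lymphoid library more inflammatory and growth factor RNA. Inflammatory myeloid genes had a median log2 ratio of −0.47 (−0.62 to −0.42), with 10 of 11 genes higher in the non-lymphoid library. Ccl3, a chemokine gene, was 927 against 1851 CPM and the cytokine gene Tnf 388 against 704 CPM. Growth factor and tissue repair genes had a median of −0.77 (−0.92 to −0.40), with Tgfb1 at 184 against 305 CPM and Pdgfb at 74.2 against 154 CPM. Cell cycle genes had a median of 0.70 (0.48 to 0.94), with 14 of 15 genes higher in the lymphoid library. Genes that other cells make rose more in the same macrophages, with medians of 4.799 for immunoglobulin constant, 2.66 for circulation and naive, 2.08 for cytotoxic granule and 1.54 for salivary secretory genes. After subtraction of free RNA, 14 of 15 cell cycle genes were still higher in the lymphoid library. The named genes Ube2c, at 66.6 against 20.8 CPM, and Prc1, at 50.1 against 19.4 CPM, also belong to cell division, while the list member Stmn1 went the other way at 61.8 against 82.3 CPM. Mgl2, a lectin gene of macrophages and dendritic cells, was 107 against 39.0 CPM, and Fcrls was 93.5 against 34.3 CPM.

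Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), the chemokine gene that draws B cells into follicles, was 118 against 0.173 CPM in macrophages, a ratio of 683 (122 to 27020) from 903 UMIs and 1 UMI. Its RNA lay in few cells, since 879 of the UMIs were in the macrophage cluster marked by Mrc1 and 1 cell held 337, without which the ratio was 429. Of the 10 named genes higher in non-lymphoid macrophages, 8 were higher in that library in all 5 classes compared, among them Fgfr2 at 66.7 against 413 CPM and Grik3 (ENSMUSG00000001985, chromosome 4, 125490700 to 125714173) at 769 against 3602 CPM. Dissociation and heat shock genes were higher in non-lymphoid macrophages in 13 of 13 genes, with a median of −0.43 (−0.53 to −0.39). The macrophages came mostly from different clusters, 65.7% of the lymphoid ones from a cluster marked by Trem2 and Tmem119 and 61.6% of the non-lymphoid ones from a cluster marked by Mmp12. The Mmp12 cluster was 17.7% of lymphoid macrophages. Its top genes also included the inflammatory genes Ccl3 and Il1a and the heat shock genes Hspa1a and Hspa1b. Within the Trem2 and the Mmp12 cluster the inflammatory median was smaller, −0.29 and −0.30, as was the cell cycle median, 0.26 and 0.19. A cluster marked by cell division genes such as Prc1 and Cenpf was 7.55% of lymphoid and 4.44% of non-lymphoid macrophages.

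In blood endothelial cells several of the genes with the largest ratios were those of venous cells. Glycam1 (ENSMUSG00000022491, chromosome 15, 103562759 to 103565081), a gene of the venules by which lymphocytes enter tissue, was 539 CPM from 1454 UMIs in the lymphoid library and had 0 UMIs in the non-lymphoid library, which makes it at least 282-fold higher against a floor of 3 counts. It came from 13 cells, 11 of them among the 181 of the venous cluster marked by Ackr1 and Selp (6.08%), of which the non-lymphoid library held only 21 cells, so that a share of up to 14.3% would be missed there, and without the cell with 505 UMIs the bound was 185. Of other genes of such venules, chosen after their values were seen, Chst4 and Fut7 were found in 8 and 6 of the 181 lymphoid venous cells and Madcam1 in 0. Ubd (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095), a gene induced by interferon gamma and tumour necrosis factor, was 464 against 1.27 CPM, a ratio of 365 (101 to 3014) from 1253 and 2 UMIs. Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001) was 1271 against 85.9 CPM, a ratio of 14.8 (12.5 to 17.7), and was also higher within the venous cluster, at 3422 against 877 CPM. The chemokine genes Cxcl9 and Cxcl10, which attract T cells and NK cells, were higher in the lymphoid library. Cxcl9 was 108 against 1.91 CPM and Cxcl10 had 243 UMIs against 1, with ratios of 56.5 (19.1 to 275) and 141 (25.1 to 5609) that rest on 3 non-lymphoid UMIs and 1 UMI. The lymphoid UMIs also lay in few cells. Cxcl9 was found in 29 of 181 venous and 13 of 489 capillary cells, and Ubd in 33 and 12. Cxcl10 was found in 11 and 15 of them, and in 3 of 125 cells of the other endothelial cluster. Fjx1, Pglyrp1, Serping1, Cytl1 and Serpinb1a were 61.7, 16.1, 13.04, 12.4 and 11.3 times as high in the lymphoid library.

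Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a target gene of the aryl hydrocarbon receptor, was higher in non-lymphoid endothelium at 2.96 against 89.7 CPM, a log2 ratio of −4.92, with all 141 non-lymphoid UMIs in the capillary cluster. Ezh2 and Ddit3 were also higher there, at 26.7 against 192 CPM and 23.7 against 99.9 CPM, and 5 of the 10 named genes of this direction were higher in all 5 classes. The median log2 ratio of all genes in endothelium was −0.10, and list medians are read against it. Interferon gamma response genes had a median of −0.44 (−0.54 to −0.34), with 10 of 13 genes higher in the non-lymphoid library, among them Iigp1 at 316 against 477 CPM and Irf1 at 274 against 365 CPM. Cxcl9 and Cxcl10 were among the 3 genes that went the other way. With free RNA subtracted this median was −0.16, while the median of −0.10 for all genes is without that subtraction. Dissociation and heat shock genes had a median of −0.51 (−0.66 to −0.41), with Dusp1 at 617 against 956 CPM. MHC class II genes had a median of 1.17 (1.00 to 1.29), with Cd74 at 1989 against 804 CPM, but this median became −0.30 when free RNA was subtracted. Free RNA was estimated at 37.8% of lymphoid against 3.17% of non-lymphoid endothelial RNA. The lymphoid estimates were only 10.3% in macrophages, 12.6% in NK/ILC1 cells and 12.2% in T cells. Why the endothelial estimate was higher was not tested, so endothelial medians after subtraction may be overcorrected. Capillary cells were 61.5% of lymphoid and 84.7% of non-lymphoid endothelial cells, and venous cells were 22.8% and 6.98%.

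**Figure D4:**
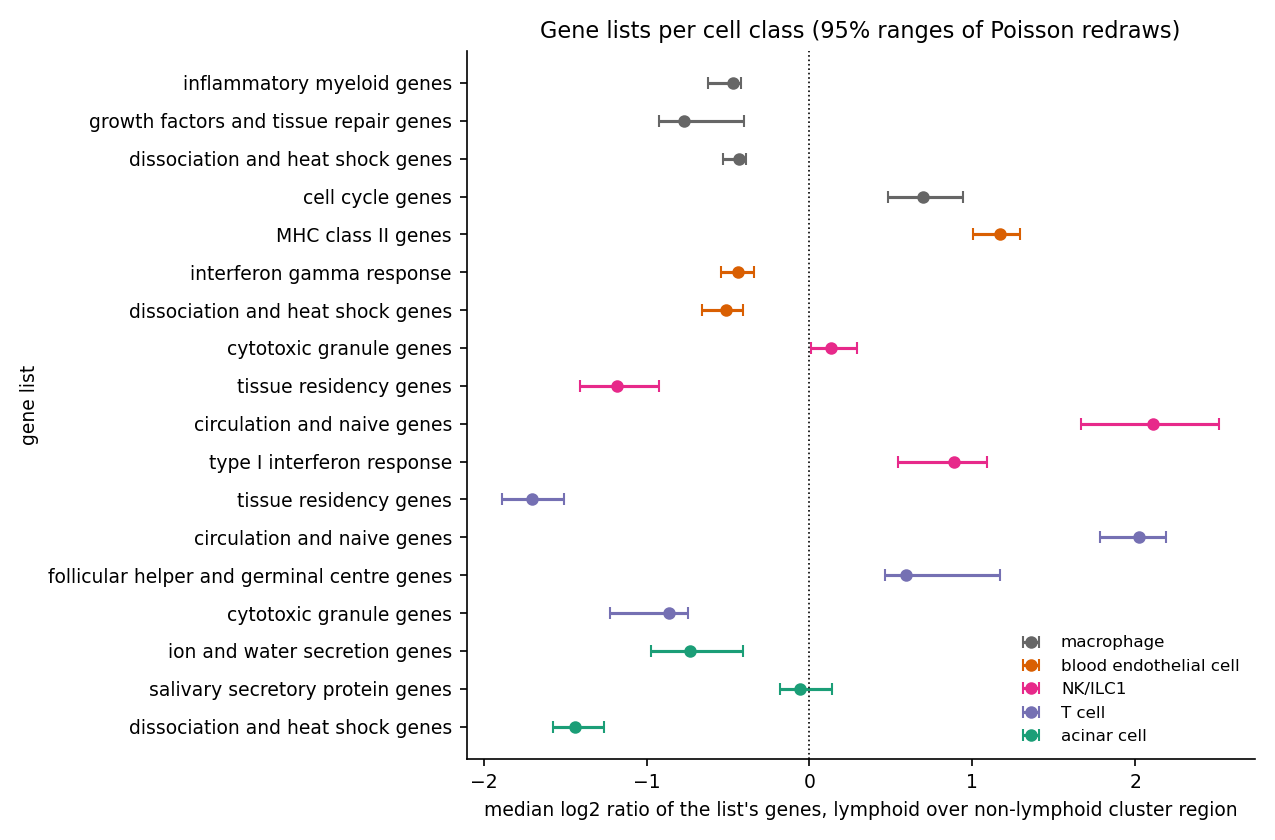
Median log2 ratio of lymphoid over non-lymphoid levels (horizontal axis) for 18 pairs of gene list and cell class (vertical axis), with 95% ranges of 200 Poisson redraws and 1 library per region. Circulation and naive genes had medians of 2.11 in NK/ILC1 and 2.02 in T cells, and tissue residency genes had medians of −1.18 and −1.71.

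Some acinar cells of the lymphoid library held saliva protein genes that were nearly or fully absent from those of the non-lymphoid library. Of the 10 named genes of this direction, Bpifa2, Dcpp1, Dcpp2 and Dcpp3 were also higher in the lymphoid library in all 5 classes. Dcpp3 (ENSMUSG00000057417, chromosome 17, 23917458 to 23919441) had 277160 UMIs, 27386 CPM, against 0 UMIs, and was at least 14212-fold higher. Dcpp2 had 162460 UMIs against 0 and was at least 8331-fold higher, while Dcpp1 was 60.9 times (53.2 to 70.0) as high. A2ml1 (ENSMUSG00000047228, chromosome 6, 128539821 to 128581608), a protease inhibitor gene, had 23900 UMIs against 0. Bpifa2 (ENSMUSG00000042459, chromosome 2, 154008265 to 154016079) was 5148 against 12.8 CPM, a ratio of 401 (259 to 656), and Muc19 (ENSMUSG00000044021, chromosome 15, 91838326 to 91934555), the gene of a salivary mucin, was 2876 against 15.4 CPM, a ratio of 187 (125 to 291). These genes were concentrated, as 90% of the UMIs of Dcpp3 lay in 8 of 255 cells, of Bpifa2 in 7 and of Muc19 in 20. Dcpp1, Dcpp2 and Dcpp3 are near-identical copies, so which copy a UMI came from is uncertain. The major secretory genes Prol1, at 42640 against 43580 CPM, and Pip, at 21970 against 15020 CPM, differed by less than 1.5 times. The salivary secretory list had a median of −0.06 (−0.18 to 0.14), with genes at 0 UMIs placed at the floor, and of 0.47 after scaling on the median of ratios.

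The median log2 ratio of all genes in acinar cells was −0.47, so lower list medians are read against that value. Ion and water secretion genes had a median of −0.73 (−0.97 to −0.41), −0.20 after scaling on the median of ratios. The sodium pump gene Atp1b1, at 365 against 719 CPM, was higher in the non-lymphoid library, while the water channel gene Aqp5 was higher in the lymphoid library at 472 against 289.7 CPM. Dissociation and heat shock genes had a median of −1.44 (−1.58 to −1.26), with Hspa1b at 14.2 against 109 CPM and Jun at 95.7 against 284 CPM. Of the named genes, the tight junction gene Cldn4 was 13.4 against 107 CPM, the Notch target gene Hes1 8.79 against 64.2 CPM, and the receptor gene Kit 14.4 against 84.8 CPM. Pcp4l1 and Ccn1 had log2 ratios of −3.77 and −3.67. The acinar cells numbered 255 and 63, all from 1 cluster.

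Over all cells, many of the genes with the largest ratios belonged to classes with a larger share. The joining chain gene of antibodies, Jchain, was 829 times (685 to 1012) as high in the lymphoid library, the B cell gene Fcmr was 746 times (206 to 6162) as high, and Ighg2c, an antibody constant gene, was at least 1321-fold higher. Dcpp3, Dcpp2, A2ml1 and Bpifa2 were again among the 10 named genes, while the direction of the acinar share depended on the processing. Higher in the non-lymphoid library were the cytokine gene Il1a at 13.9 against 116 CPM, the heat shock gene Hspa1b at 189.7 against 1494 CPM, the endothelial gene Adgrl4 at 31.6 against 241 CPM, the pericyte gene Rgs5 and the macrophage fusion gene Dcstamp, with log2 ratios between −3.06 and −2.90.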

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

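Most results kept their direction. Restrictions to parts of a class or to fewer genes, the change of the limit for a second lineage and the denominators without unnamed clusters were tests chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible because each region had 1 library, and the shared replicate number 1 does not link them. Of 85 alternatives for class shares 73 stayed within the counting interval, of 6 for subclasses all 6, of 34 for the sets of named genes 29 kept most genes and their direction, of 9 for Gzma in NK/ILC1 cells 5 and of 152 for gene lists 106 stayed within their ranges, of 580 for single named genes 503, and of 8 for the cells that hold Gzma 4. All Gzma ratios in NK/ILC1 cells stayed above 1. Depth limits the smallest classes, since non-lymphoid NK/ILC1 and acinar cells numbered 64 and 63. Where no cause is given below, the cause was not tested.

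The ratio of the acinar share, 0.408 in the report, was 1.09 with at least 500 genes, 1.56 and 0.994 with at most 5% and 20% mitochondrial UMIs, 5.37 with doublets kept, 1.06 at resolution 2.0, 5.02 with each library clustered alone and 1.30 with 50 principal components. In these settings most cells of an unnamed lymphoid cluster of 614 cells, which held secretory RNA and Cd3e or C1qa in many cells, took the acinar name, for example 477 of 614 with doublets kept. With doublets kept and with libraries alone, only 12 and 15 non-lymphoid cells had that name, and the cause was not tested. The macrophage share ratio of 0.304 became 0.377 with at least 500 genes, 0.388 and 0.345 at resolutions 0.5 and 2.0, 0.413 with libraries alone and 0.408 with 50 principal components. There the monocyte and dendritic cell cluster of 463 cells was named in part or mostly as macrophages, alone or with monocytes, for example 457 cells at resolution 0.5, so its own share could not be given in those 5 settings. Acinar levels with doublets kept were not run, as too few cells were left.

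With at least 50 UMIs and 100 CPM, 9 of the 20 named genes of macrophages and of acinar cells passed and 10 each of blood endothelial, NK/ILC1 and T cells, by construction of the stricter limit. Hbb-bs in T cells had a log2 ratio of −4.26 with at least 500 genes. In the main setting 1 lymphoid cell held 1264 of its 1266 UMIs and no non-lymphoid T cell held any. The value of −4.26 may thus only reflect the floor of 3 counts and is not read as a higher non-lymphoid level. Whether the 1 cell left the class was not tested. The Gzma ratio in NK/ILC1 cells was 5.04 from the mean CPM of cells, 3.12 with at least 500 genes, 5.35 in cells gated by UMIs and 1.73 in the Gzmc subcluster. Gzma was seen in 44.3% of lymphoid NK/ILC1 cells with at least 2 UMIs and in 39.4% after thinning, and in 0.432% and 0.606% of lymphoid T cells.

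With at least 500 genes, list medians were −0.75 for inflammatory, −0.33 for repair and 0.41 for cell cycle genes in macrophages, −0.0628 for cytotoxic and 2.89 for circulation genes in NK/ILC1 cells, and −0.25 for secretory and −0.42 for dissociation genes in acinar cells. With free RNA subtracted they were −0.40 for inflammatory and −0.39 for dissociation genes in macrophages, −0.30 for MHC class II, −0.16 for interferon gamma and −2.05 for dissociation genes in endothelium, and −1.95 for dissociation genes in acinar cells. The sign of the endothelial MHC class II median thus depends on how much free RNA is subtracted. The estimate was 37.8% in lymphoid endothelium, against 10.3% to 12.6% in lymphoid macrophages, T cells and NK/ILC1 cells. The endothelial medians after subtraction may therefore be overcorrected. With immunoglobulin, ribosomal, mitochondrial and secretory genes left out, or with median-of-ratios scaling, the medians were 1.31 and 1.31 for MHC class II, −0.30 and −0.30 for interferon gamma and −0.37 and −0.37 for dissociation genes in endothelium. In acinar cells they were −0.21 and −0.20 for ion and water, 0.46 and 0.47 for secretory, and −0.92 and −0.91 for dissociation genes, and the second scaling by construction takes away a shift of −0.14 in endothelial and −0.53 in acinar cells. The mean CPM of cells gave −0.40 for inflammatory genes, 0.90 for MHC class II and 1.08 for secretory genes. Kept doublets gave 0.83 for MHC class II, and no UMI filter gave −0.19 for secretory genes.

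Within clusters most of the changed medians lay closer to 0. In the Trem2 and the Mmp12 macrophage clusters they were −0.29 and −0.30 for inflammatory, −0.0767 and −0.15 for dissociation and 0.26 and 0.19 for cell cycle genes. In capillary endothelium they were −0.34 for interferon gamma and −0.24 for dissociation genes. In the Gzmc subcluster residency genes had −0.46 and type I interferon genes 1.54, against −0.20 for the latter in the Klra8 subcluster. In CD8 T cells circulation genes had 2.80 and cytotoxic genes −0.10. In the Zfp683 T cluster residency genes had −0.68, circulation genes 0.42, follicular helper genes 0.18 and cytotoxic genes 0.37.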

Other observations

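The tests of free RNA in acinar cells, of the library preparations, of acinar cells of another type, of the mix of subclusters and of clustering on Gzma were chosen after the results they measure were seen, and the reading of receptor segments was added after the data were seen. Plasma cells of the lymphoid cluster region came from few receptor combinations. Among 680 plasma cells with both chains called, the 5 most frequent pairs of heavy and light chain segments held 322 cells, 47.4%, against 65 of 983 B cells, 6.61%. The pair Ighv1-53 with Igkv3-5 was seen in 75 plasma cells, 11.03% (8.78 to 13.6), where independent pairing would give 12.3, and Ighv3-6 with Igkv3-1 in 71, where it would give 9.61. These plasma cells mostly carried IgM, the first class of antibody, since the constant gene Ighm led in 626 of 735 cells, 85.2%, followed by Ighg2c in 75 and Ighg2b in 21. Of the plasma cells with Ighv1-53 and Igkv3-5 and a constant gene called, 61 of 61 had Ighm, as did 70 of 71 with Ighv3-6 and Igkv3-1.

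T cells also shared receptor segments. In the lymphoid CD4 subcluster marked by Il21, Trbv4 with Trav9-1 was in 37 of 180 cells, 20.6% (14.9 to 27.2), where independent pairing would give 8.02. In the CD8 subcluster that held the non-lymphoid Gzma, Trbv1 with Trav7d-3 was in 23 of 62 lymphoid cells, 37.1% (25.2 to 50.3), and the most frequent non-lymphoid pairs were Trbv1 with Trav12-2 in 9 and Trbv29 with Trav3-3 in 8 of 28 cells. Among the naive CD8 T cells, the most frequent pair was in 2 of 120 cells. Segment pairs are not full receptor sequences, and 1 library per region does not show whether such pairs recur between animals.

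A set of 32 genes, among them Gm15564, Il31ra, Fgfr2, Lars2, Grik3 and Tmtc2, was at least 2 times as high in the non-lymphoid library in each of the 5 classes compared. Free RNA, which adds a like number of UMIs to every droplet, is argued against, since the log2 ratio of CPM in shallower over deeper non-lymphoid cells had a median of −0.12 (−0.18 to 0.05) over genes and the 4 classes other than acinar cells, and of 0.86 for the free RNA marker Mucl2, which ranged from −0.15 to 0.96 between classes. Depth is argued against as well, as the median log2 ratio was −2.00 with lymphoid cells at least as deep as the non-lymphoid median, and −1.71 in all cells. The class medians lay between −1.97 and −1.65, a range of 0.319. The genes were chosen for a shift in every class, which largely sets such a small range, so no conclusion is drawn from it. A difference between the library preparations and one between the regions cannot be told apart with 1 library each. No statement about a single class is drawn from these genes.

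Dcpp2, Dcpp3, A2ml1, Muc19 and Bpifa2 were far higher in lymphoid than in non-lymphoid acinar cells, and Dcpp3 was also seen in 37.6% of the other named lymphoid cells. Free RNA is argued against for all 5, as in acinar cells picked by Muc19, Bpifa2 or A2ml1 without the tested gene each was far higher relative to Mucl2 than in the other classes of that library, with Dcpp2 lowest at 141.5 times (139.6 to 143.4), although over all acinar cells Dcpp2 reached only 1.46 times. A higher level in every acinar cell is argued against as well, as Dcpp2 and Dcpp3 in the 213 acinar cells with little Muc19, Bpifa2 or A2ml1 were 0.00225 times the level in the other 42. Over 0.5% of UMIs came from Muc19, Bpifa2 or A2ml1 in 12.9% (9.08 to 17.7) of lymphoid acinar cells, 33 of 255, and in 0 of 63 non-lymphoid cells, and these 33 cells held Mucl2 at 26925 CPM against 394420 CPM in the other 222. The lymphoid sample may therefore have held acinar cells of another type, such as those of an adjoining gland, which remains a hypothesis from the same data.

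Gzma in NK/ILC1 cells was weighed against a change in their composition. T cells or doublets in the class are argued against, as the ratio was 6.06 (4.95 to 7.49) without cells that had a Cd3e, Cd3d, Cd3g, Cd79a or Ms4a1 UMI. Clustering on Gzma itself is argued against, as the ratio was 5.35 (4.37 to 6.61) in 275 and 45 cells picked by Ncr1 or Klrb1c UMIs without those genes and without use of clusters. The different mix of the Klra8 and Gzmc subclusters and a higher level within them cannot be told apart. The ratio of 1.73 in the Gzmc subcluster rests on 12 of 96 and 8 of 51 cells, shares of 12.5% and 15.7% that go the other way. The Klra8 subcluster had 13 non-lymphoid cells. A candidate explanation is that the region's NK/ILC1 cells are mainly circulating NK cells, rich in Gzma in the lymphoid library only, while resident cells rich in Gzmb prevail elsewhere, which these data did not test and which staining of granzyme A with Itga1 and Itga2 protein in sections of further animals could test.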
